A study of Saccharomyces cerevisiae x Saccharomyces paradoxus and Saccharomyces cerevisiae and Saccharomyces paradoxus with 10 samples.

How the data were processed

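The series measured poly-A selected mRNA and ribosome-protected fragments (RPF, the stretches of mRNA that translating ribosomes shield from nuclease) in a hybrid of the yeasts Saccharomyces cerevisiae and Saccharomyces paradoxus and in its parents. Per the labels' protocols, the hybrid was a diploid cross of the S. cerevisiae strain BY4176 and the S. paradoxus strain CBS432, the S. cerevisiae parent was haploid and the S. paradoxus parent diploid, although the description of the mixed mRNA library also speaks of haploid strains. Cultures were started from single colonies, grown in rich medium at 30 °C and collected at an optical density of 0.5 to 0.7. RPF were taken from single-ribosome fractions of a gradient. The 10 samples formed 4 settings, namely hybrid mRNA, hybrid RPF, parental mRNA and parental RPF, with 2 replicates each. Parental RPF came from mixed parents, with replicate 2 sequenced in 2 lanes, and parental mRNA came from 1 mixed library and 1 library of each parent. Which of the parental mRNA replicates was the mixed library was not given in the sources used here, and neither was the way in which the lanes were combined. No label said whether replicates were separate cultures, so p-values measured only the spread between these samples, which may be technical.

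The values used were signal, namely the total base-level coverage of each gene over its unmasked bases, as the authors deposited it for the allele or gene of each species. Per the file's description, the S. paradoxus coverage was multiplied by the authors by 1 factor per replicate so that both species had the same total. That factor was 2.13 in parental RPF replicate 1 and 0.417 in replicate 2, and lay between 0.859 and 1.01 elsewhere. This scaling removes any difference in total output between species. Gene pairs and annotation came from a published comparison of the genus, per the file's description, and CASAVA 1.8.2 and Bowtie 0.12 were named in the submitters' processing notes. The genome builds were not given in the sources used here. The authors also deposited an adjusted p-value and a call per gene from their own permutation test, the larger p of both replicates, for genes with at least 100 reads. Other deposited columns held the number of unmasked bases, sequence divergence and TATA-box and ploidy marks, which the authors took from alignments and published sets. A further 24 columns of values per sample were not used.

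Coverage counts each base of each read, so it is not a count of reads or molecules, and how many reads stood behind a value was unknown. Total coverage as deposited ran from 60.6 Mb in hybrid RPF replicate 2 to 167 Mb in hybrid mRNA replicate 2. With the authors' factors undone, the lowest and highest totals were those of S. paradoxus in parental RPF, at 49.8 Mb in replicate 1 and 256 Mb in replicate 2. The tests planned before the data were examined assumed read counts or, failing that, a log-scale test, and the log-scale test was used because the values were coverage. Each of the 16 columns was expressed in ppm of its total, 0.5 was added and the log2 taken, which understates the differences of weakly covered genes. Of 4637 genes, 4544 had a mean coverage of at least 3 ppm and were tested. The table had 3 blank lines, and 235 genes had no systematic name and are given under the identifiers of the table. Coordinates are those of the R64 annotation of S. cerevisiae and were matched by systematic name.

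For each replicate the log2 ratio of S. cerevisiae over S. paradoxus was formed, and limma 3.58.1 in R 4.3.3 fitted 1 mean per setting with a spread that followed mean coverage. The ratios left 4 residual degrees of freedom, shared over all settings. In the hybrid both alleles share 1 cell, so an allele difference there is called cis. A parental difference is that between the species, and the parental minus the hybrid difference is called trans. Translational efficiency (TE) is the RPF ratio minus the mRNA ratio, tested as an interaction in the same fit. P-values were two-sided, adjusted by the Benjamini-Hochberg method, and called under 0.05. Errors are standard errors from this fit, with n = 2 replicates per setting. They rest on the spread shared over all settings, so a gene has the same error in mRNA and in RPF. For most genes they are therefore too wide for mRNA and too narrow for RPF.

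Replicate ratios differed by a median of 0.17 in hybrid mRNA, 0.35 in hybrid RPF, 0.19 in parental mRNA and 0.33 in parental RPF on the log2 scale, so that 1 shared spread was too wide for mRNA and too narrow for RPF. In simulated data with 200 genes of 4544 changed 2-fold, the shared spread gave 32.8% false calls for cis RPF, 18.4% for parental RPF and 22.6% for trans RPF, and 0% for cis mRNA. A fit that weighted each setting by its own spread, chosen after the replicate differences had been seen, gave 10.5%, 6.3%, 0% and 4.3% in the same order. It recovered 0.2% of the 2-fold trans RPF changes, against 32.6% with the shared spread. For cis TE the false share was 11.1% with the shared spread and 13.1% with weights when mRNA was changed. Of the 2-fold changes, 30.4% and 25.1% were recovered there. For trans TE neither fit recovered a 2-fold change. False shares depend on the number and size of the simulated changes, so they are not those of the calls in the real data. The planned fit was kept and the weighted count of genes is printed beside that of each comparison, but not beside the counts within gene lists. With weights the list counts moved by differing amounts. In parental mRNA, higher methionine and sulfur genes went from 7 to 16 and lower respiratory genes from 22 to 23. All of the genes named for the largest changes passed both fits.

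Named genes followed a rule fixed before the data were examined. For cis mRNA and cis TE it took the 8 largest differences in each direction, and for other comparisons 5, among called genes with a mean coverage above the median of 106 ppm and with the same direction in every replicate or pair of replicates. Up to 4 members with the smallest p were added from each list described, together with URA3 and the mating genes. The 30 gene lists, also fixed beforehand, were tested with limma's camera at a preset correlation of 0.01 and adjusted over 270 tests. Of 51 list calls, 0 held with an estimated correlation, which rests on 4 residual degrees of freedom, and 46 held with setting weights. In a check on 1000 random lists in simulated data without change, for cis mRNA, 3.3% had a p under 0.05. Genes were simulated without correlation, so this check could not show whether 0.01 is too low for the lists used. Slopes across genes took each variable from a different replicate so that no error was shared, with intervals from 1000 bootstrap draws over genes. On simulated ratios a true slope of 0.6 came out as 0.602 and a slope of 1 as 0.999.

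Alternatives covered the scaling, the coverage filter, the pseudocount, an offset for unmasked length, the library block, the replicates as a block, a test against a 1.5-fold difference, subsets of the libraries and each replicate left out. Near-identical paralogs share reads, and the table held 21 of the 137 cytosolic ribosomal protein genes listed. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and plots.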

Results

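Allele-specific mRNA and ribosome-protected fragment (RPF) coverage was measured in a hybrid of S. cerevisiae and S. paradoxus and in both parents, to separate differences between the species that act in cis from those that act in trans, at the level of mRNA and of translation. Each of the 4 settings had 2 replicates, and 4544 genes were compared. Total coverage per species column, after the authors' scaling, ran from 60.6 to 167 Mb, and before it from 49.8 Mb to 256 Mb, both in parental RPF. Genes named for the largest differences had a mean coverage above 106 ppm of the column total, and larger values of weaker genes are mostly not given. Replicate ratios correlated across genes with r = 0.83 in hybrid mRNA, 0.54 in hybrid RPF, 0.94 in parental mRNA and 0.87 in parental RPF, and genes are not independent replicates. All log2 values are S. cerevisiae over S. paradoxus.

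URA3, the orotidine-phosphate decarboxylase gene that the labels give as replaced in both strains crossed to make the hybrid, had a mean coverage of 196 ppm of the column total in the 8 parental columns and 9.09 in the 8 hybrid columns, a 21.6-fold difference in the direction of the labels. The lowest parental value was 164 and the highest hybrid value 12.5. LYS2, which the labels also give as a deleted or mutated marker in strains of the series, was not analysed here. Genes of the mating programme separated the S. cerevisiae parent from the other strains. STE3, the a-factor receptor, stood at 855 and 854 ppm in S. cerevisiae parental mRNA, at 6.48 and 5.85 in the S. paradoxus parent, and at 0.794 and 2.2 for the S. cerevisiae allele of the hybrid. Per the labels' protocols the parents differed in ploidy as well as in species, although 1 description speaks of haploid strains. Ploidy was not tested apart from species in any parental or trans value given here. Parents and hybrid also differed in URA3, and what this difference does to trans values was not tested. Nor was any effect of the LYS2 marker on parental or trans values. Without the genes marked for ploidy or mating type, 1713 genes instead of 1752 differed in parental mRNA.

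**Figure D1:**
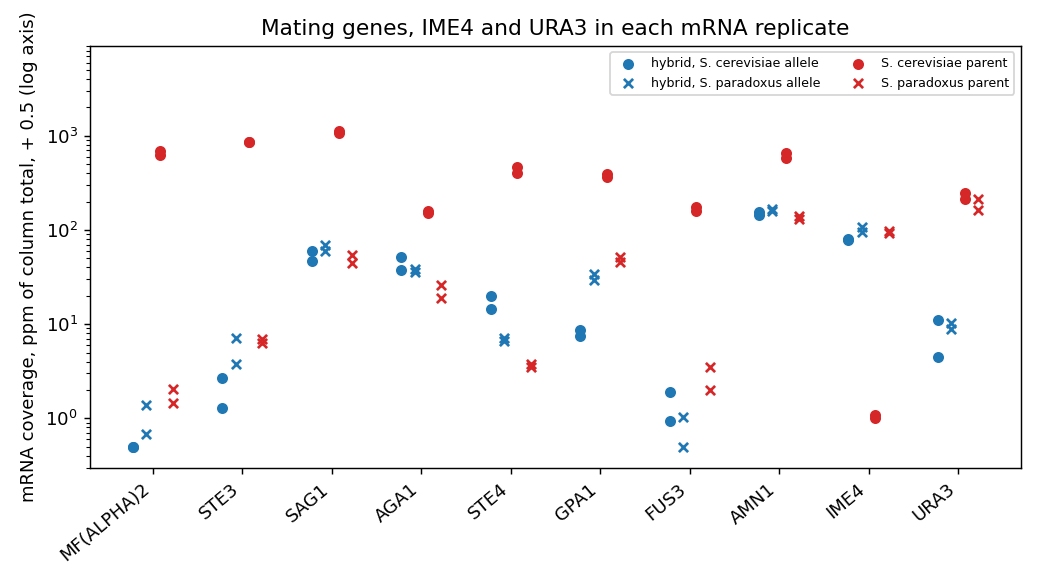
Coverage in ppm of the column total plus 0.5 (log axis) of mating genes, IME4 and URA3 in mRNA, with 1 point per replicate for each species column of the hybrid (blue) and the parents (red). STE3 lay at 855 and 854 in the S. cerevisiae parent and at 6.48 and 5.85 in the S. paradoxus parent.

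Within the hybrid, the S. cerevisiae allele of LYS21, which encodes a homocitrate synthase of lysine synthesis, gave 6.99-fold more mRNA than the S. paradoxus allele (log2 2.81 ± 0.22 SE, n = 2). BDH2, a putative dehydrogenase gene, differed in the same direction by 7.78-fold (2.96 ± 0.33), and TPO4, a polyamine transporter gene, by 5.56-fold (2.48 ± 0.16). The S. paradoxus allele was higher for RTA1 (log2 -4.20 ± 0.26, 18.4-fold), for the glutathione transferase gene GTT1 (-3.32 ± 0.19, 9.97-fold) and for YPL088W (-3.14 ± 0.29, 8.83-fold). RTA1 (YGR213C) lies on chromosome VII at 918512 to 919465, GTT1 (YIR038C) on chromosome IX at 423809 to 424513 and LYS21 (YDL131W) on chromosome IV at 227393 to 228715, all as coding genes of the R64 annotation. Further genes with a higher S. cerevisiae allele were GLO2 for glyoxalase II (2.10 ± 0.23), LYS12 for homoisocitrate dehydrogenase (2.09 ± 0.14), YJL133C-A (1.83 ± 0.28) and the zinc transporter gene ZRT1 (1.78 ± 0.43). Lower in S. cerevisiae were YLR040C (-1.90 ± 0.33), the alcohol dehydrogenase gene ADH5 (-1.83 ± 0.31), the glutathione peroxidase gene GPX2 (-1.68 ± 0.16) and ARG3 for ornithine carbamoyltransferase (-1.58 ± 0.31). The glutathione reductase gene GLR1 (2.33 ± 0.16) and the ribosomal protein gene RPL9B (-1.50 ± 0.16) differed in the number of unmasked bases between species, and with an offset for that length their values were 0.45 (adjusted p = 0.14) and -0.41 (adjusted p = 0.12).

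In limma, 600 genes differed between alleles in mRNA (13.2% of those tested), 272 higher for S. cerevisiae and 328 higher for S. paradoxus. With each setting weighted by its own spread the count was 1727, of which 808 and 919. Without hybrid mRNA replicate 1 the count was 75, and without replicate 2 it was 44. Against a difference of at least 1.5-fold, 59 genes passed, and ZRT1, YLR040C, ADH5 and ARG3 did not. Without replicate 1 and without replicate 2 the calls were lost for ZRT1 (1.57 and 1.98), ADH5 (-1.86 and -1.80), ARG3 (-1.31 and -1.85) and YJL133C-A (1.81 and 1.84), and without replicate 2 for YLR040C (-1.35). Leaving out a replicate also drops the hybrid mRNA spread, the narrowest of the settings, from the shared one. Lower counts and lost calls therefore need not mean that the replicates disagreed, and the values of ADH5 and YJL133C-A hardly moved. The spread of any setting left with 1 replicate is dropped in the same way below. With the hybrid libraries alone ZRT1 had an adjusted p = 0.056. Of the 8 genes of lysine synthesis tested, 4 had a higher S. cerevisiae allele and LYS5 a lower one (-1.12 ± 0.28), and 5 and 1 passed when adjusted over the list alone. LYS1 was among the higher ones (0.80 ± 0.18). Camera gave this list an adjusted p = 0.028, and adjusted p = 0.5 with an estimated correlation. The authors' deposited table called 2734 genes for mRNA cis, of which 575 were among the 600 and 1644 among those of the weighted fit.

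In hybrid RPF the allele differences of LYS21 (3.73 ± 0.22, 13.3-fold) and GLO2 (2.64 ± 0.23, 6.22-fold) had the direction seen in mRNA, as did those of RTA1 (-3.89 ± 0.26, 14.8-fold) and YPL088W (-3.89 ± 0.29, 14.9-fold). ZRT1 reached 4.40 ± 0.43 (21.1-fold), the uncharacterised gene Scer_2.323 4.54 ± 0.53 and RFS1 2.5 ± 0.29. These moved with the library, with replicate values of 3.08 and 5.73 for ZRT1, 6.17 and 2.92 for Scer_2.323 and 1.77 and 3.23 for RFS1. The errors printed for RPF rest on the spread shared with mRNA and are too narrow for replicate differences of this size. The S. paradoxus allele was higher for BRE4 (-3.88 ± 0.35, 14.7-fold) and Scer_11.26 (-3.27 ± 0.25, 9.68-fold), with -2.85 for BRE4 without hybrid RPF replicate 1 and -4.90 without replicate 2. YLR046C had the value -7.25 ± 0.50, but its S. cerevisiae allele was listed at 0 in 1 replicate and no fold is given (-6.39 without hybrid RPF replicate 1 and -8.11 without replicate 2). In limma 1175 genes were called, 541 higher for S. cerevisiae and 634 for S. paradoxus, and 552 with setting weights (260 and 292). Without hybrid RPF replicate 2 the count was 707, and 193 genes passed against a 1.5-fold difference. Among 22 genes of general stress and reserve carbohydrate, 10 had a higher S. paradoxus allele and 4 a higher S. cerevisiae allele (12 and 4 adjusted over the list alone). GTT1 (-2.80 ± 0.19), GPX2 (-2.13 ± 0.16) and the thioredoxin gene TRX2 (-1.52 ± 0.15) were lower, and GLR1 was higher (2.25 ± 0.16), but not with the offset for unmasked length (0.37, adjusted p = 0.16). The list had an adjusted p = 0.029 in camera and adjusted p = 0.69 with an estimated correlation.

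The mRNA and RPF ratios of the hybrid came from separate libraries. Of the genes called in either, 356 were called in both, and 352 of these had the same direction. Higher for S. cerevisiae in both were 165 genes, against 32.4 for independent lists, and higher for S. paradoxus 187, against 45.8. With setting weights 396 genes were called in both and 390 had the same direction. Calls in mRNA and RPF used the same spread per gene, which alone can raise the number called in both. This also holds for the parental and trans overlaps given below.

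**Figure D2:**
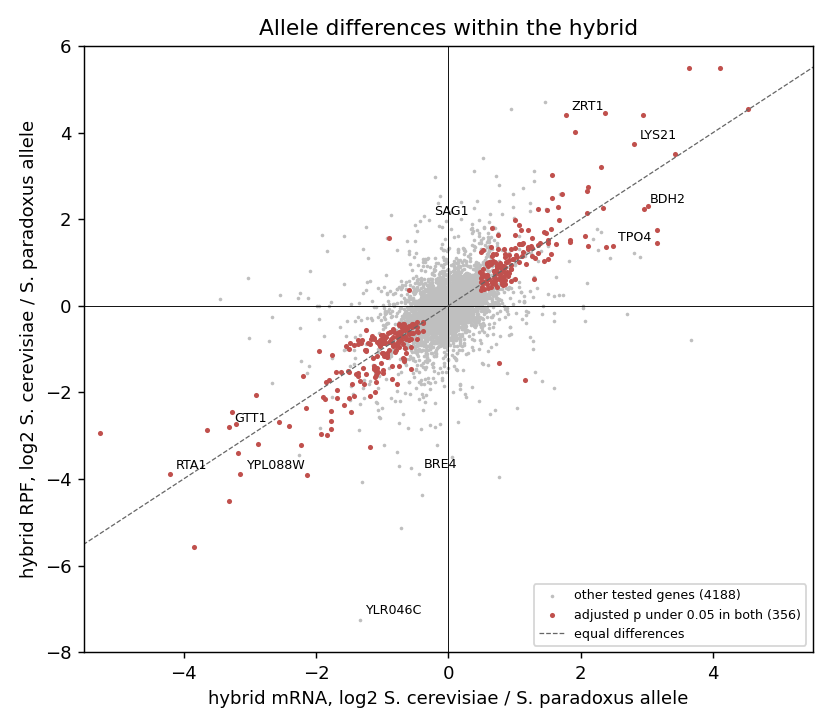
Each point is 1 of 4544 genes, with the log2 allele ratio in hybrid mRNA on the x axis and in hybrid RPF on the y axis, both as means of 2 replicates. Red points are the 356 genes called in both, and the dashed line marks equal differences.

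Few genes were called for an allele difference in translational efficiency, the RPF ratio relative to the mRNA ratio. In simulated data the shared spread recovered 30.4% of 2-fold changes when mRNA was changed and 33.7% when RPF was. Genes that were not called may therefore differ too. BRE4 was lower for S. cerevisiae by -3.43 ± 0.50 (10.7-fold, adjusted p = 0.02), Scer_11.26 by -2.09 ± 0.35, the mannosyltransferase gene KTR4 by -1.30 ± 0.21 and MRT4, which acts in ribosome assembly, by -1.29 ± 0.22. Higher for S. cerevisiae were the bud-site gene BUD3 (1.14 ± 0.21), IDP1 for mitochondrial isocitrate dehydrogenase (0.96 ± 0.18) and LYS4 for homoaconitase (0.96 ± 0.18). YLR046C (-5.91 ± 0.71) had its S. cerevisiae allele listed at 0 in 1 hybrid RPF replicate. SAG1 (2.25 ± 0.35) rested on almost no hybrid RPF coverage, with the S. paradoxus allele listed at 0 in both replicates and the S. cerevisiae allele at 1.39 and 1.52 ppm, and it lost its call with the pseudocount doubled (1.58, adjusted p = 0.057). These 9 were all the genes that met the naming rule, on either side of 0.

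For cis TE limma called 20 genes, 8 higher and 12 lower for S. cerevisiae, with 795 at an unadjusted p under 0.05, and the weighted fit called 64 (28 and 36). Leaving out 1 library also drops its spread from the shared one, and the count depended on single libraries. It was 634 without hybrid RPF replicate 1 and 89 without replicate 2. In limma it was 0 without hybrid mRNA replicate 1 (463 at an unadjusted p under 0.05) and 0 without replicate 2 (284), so that each of the 9 named calls was lost there, with directions kept and adjusted p from 0.14 to 0.63. Without hybrid RPF replicate 2 the calls of LYS4 (0.90) and MRT4 (-1.07) were lost. With the hybrid libraries alone, where 12 genes passed, SAG1 (adjusted p = 0.19), BUD3 (0.055), LYS4 (0.052) and BRE4 (0.052) did not. Without hybrid RPF replicate 1 and without replicate 2 BRE4 had -2.40 and -4.45, and YLR046C -5.04 and -6.77. Against a 1.5-fold difference 3 genes passed, and of the 9 named only YLR046C, with BRE4 at an adjusted p = 0.071, SAG1 at 0.15, Scer_11.26 at 0.2, KTR4 and MRT4 at 0.45, BUD3 at 0.92 and IDP1 and LYS4 at 1. Among 18 nitrogen catabolite genes 0 passed in limma, 6 were higher for S. cerevisiae at an unadjusted p under 0.05, and 4 passed adjusted over the list alone. The largest values were those of the urea transporter gene DUR3 (3.09 ± 0.72, adjusted p = 0.076) and the ammonium transporter gene MEP2 (3.08 ± 0.79, adjusted p = 0.093). The S. paradoxus allele of each was listed at 0 in 1 hybrid RPF replicate, and without hybrid RPF replicate 1 and without replicate 2 the values were 1.83 and 4.35 for DUR3 and 4.41 and 1.75 for MEP2. Camera gave the list an adjusted p = 0.025, and adjusted p = 0.59 with an estimated correlation. The authors' deposited table called 1276 genes for translation cis, of which 13 were among the 20 and 34 among the 64. All 1276 had the same sign as in the limma fit.

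**Figure D3:**
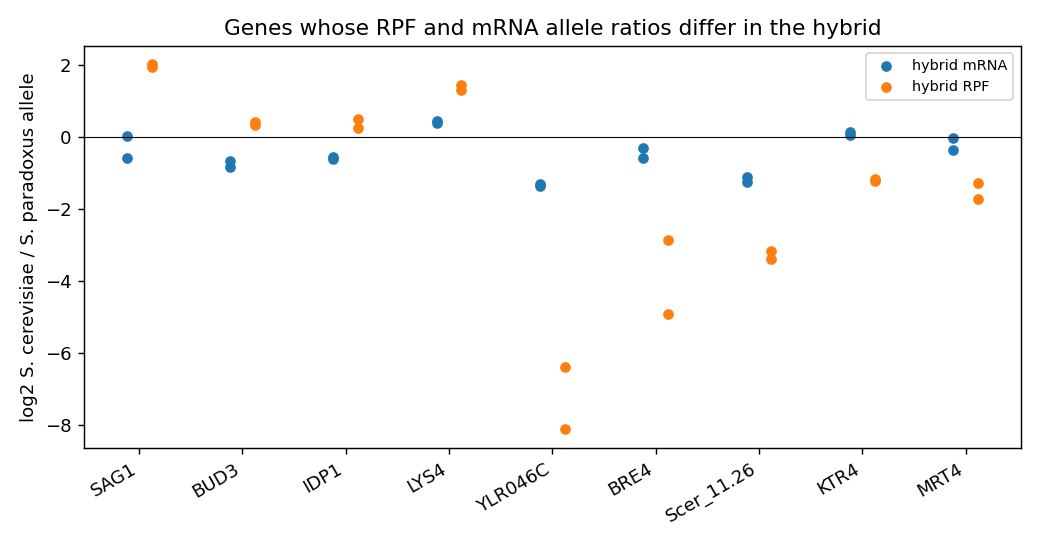
Log2 allele ratios of the 9 genes named for cis translational efficiency, with 1 point per replicate for hybrid mRNA (blue) and hybrid RPF (orange). For KTR4 the fitted TE difference was -1.30 and for BUD3 1.14.

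Between the parents, mating genes were far higher in S. cerevisiae mRNA. MF(ALPHA)2, which encodes alpha-factor, differed by 379-fold (log2 8.57 ± 0.50), STE3 by 128-fold (7.0 ± 0.48) and YLR040C by 23.2-fold (4.53 ± 0.33). In the S. paradoxus parent MF(ALPHA)2 stood at 1.53 and 0.97 ppm, so its fold depends on the 0.5 added. Outside the mating genes, BDH2 was 27.3-fold higher in S. cerevisiae (4.77 ± 0.33) and the serine and threonine deaminase gene CHA1 25.2-fold (4.65 ± 0.14). Lower in S. cerevisiae were RTA1 (-6.29 ± 0.26, 78.4-fold), ARG3 (-4.50 ± 0.31), Scer_14.442 (-4.26 ± 0.23), YPL088W (-4.15 ± 0.29) and YLR046C (-4.02 ± 0.50). Of 22 haploid and mating genes, 18 were higher in S. cerevisiae and 4 did not pass, with the same 18 when adjusted over the list alone and a list median of 2.90. STE4 (6.88 ± 0.71), GPA1 (2.97 ± 0.31) and FUS3 (5.96 ± 0.77), all of the pheromone pathway, were among them, whereas STE2 had -0.25 ± 0.69 and STE6 -0.21 ± 0.67. The list had an adjusted p = 1.5e-07 in camera and adjusted p = 0.21 with an estimated correlation.

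Genes of ribosome biogenesis were lower in S. cerevisiae parental mRNA, where 84 of 100 passed (88 lower and 1 higher adjusted over the list alone) with a list median of -0.71. NSR1, for the nucleolin-like protein, had the value -2.60 ± 0.12, NOG1 -1.47 ± 0.14 and SPB1 -1.32 ± 0.13. Camera gave an adjusted p = 3.4e-18, and adjusted p = 0.62 with an estimated correlation. Of 26 genes of the respiratory chain and ATP synthase 22 were lower, and 22 also adjusted over the list alone, with a list median of -1.11. Examples were the cytochrome c gene CYC1 (-2.76 ± 0.15, 6.78-fold), RIP1 (-2.34 ± 0.15) and CYT1 (-1.79 ± 0.11). The list had an adjusted p = 2.3e-09, and adjusted p = 0.23 with an estimated correlation. Of 20 genes of ergosterol synthesis 13 were lower and 1 higher (14 and 1 adjusted over the list alone), among them ERG28 (-2.23 ± 0.13) and ERG5 (-1.38 ± 0.13), with an adjusted p = 0.00021 in camera and adjusted p = 0.53 with an estimated correlation.

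Phosphate genes were higher in S. cerevisiae parental mRNA, with 9 of 13 past the test on all genes and 9 adjusted over the list alone. The polyphosphate synthesis gene VTC4 reached 2.28 ± 0.12, VTC1 2.15 ± 0.13 and the phosphate transporter gene PHO84 2.06 ± 0.17. Camera gave an adjusted p = 8.6e-05, and adjusted p = 0.23 with an estimated correlation. Of 25 genes of methionine and sulfur metabolism 7 were higher and 2 lower, likewise 7 and 2 adjusted over the list alone, led by MET17 (2.49 ± 0.13) and MET6 (1.33 ± 0.13). The list had an adjusted p = 0.038, and adjusted p = 0.5 with an estimated correlation. Among 67 genes listed as mitochondrial ribosomal proteins 25 were lower and 5 higher (26 and 5 adjusted over the list alone), with MRPS35 at -1.02 ± 0.14 and MRP8 at 1.56 ± 0.24. Members were taken by gene name, and whether MRP8 belongs to that ribosome was not checked. Camera gave the list an adjusted p = 0.0032, and adjusted p = 0.59 with an estimated correlation.

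In all, 1752 genes differed between the parents in mRNA, 899 higher and 853 lower in S. cerevisiae, and 2663 with setting weights (1398 and 1265). With median-of-ratios scaling 803 were higher and 956 lower, so the balance turned. Without parental mRNA replicate 1 the count was 824 and without replicate 2 it was 663. Against a 1.5-fold difference 410 genes passed.

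**Figure D4:**
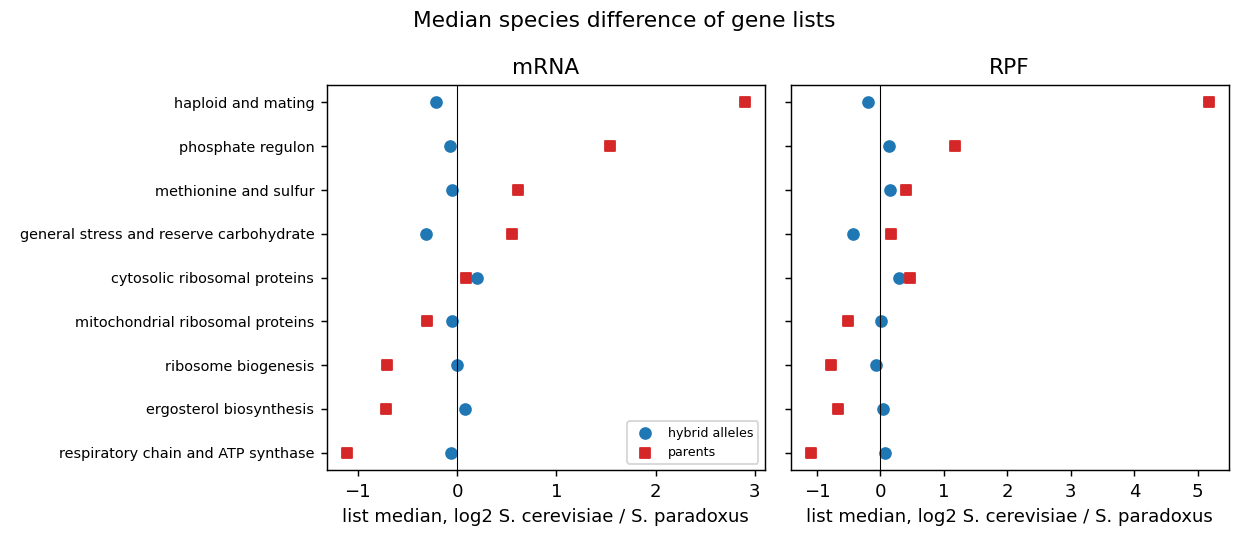
Median log2 S. cerevisiae over S. paradoxus of 9 gene lists in mRNA (left) and RPF (right), for the hybrid alleles (blue circles) and the parents (red squares). In parental mRNA the medians ran from -1.11 for the respiratory chain and ATP synthase to 2.90 for haploid and mating genes.

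Among genes with a mean above 106 ppm, mating genes were again far higher in S. cerevisiae parental RPF. MF(ALPHA)2 was 640-fold (9.32 ± 0.50), SAG1 for alpha-agglutinin 437-fold (8.77 ± 0.25), STE3 262-fold (8.03 ± 0.48) and AGA1 84.0-fold (6.39 ± 0.42) higher. In S. paradoxus parental RPF MF(ALPHA)2 stood at 1.31 and 1.21 ppm and STE3 at 0.622 and 2.8, so their folds depend on the 0.5 added. Scer_2.323 was 47.7-fold higher (5.58 ± 0.53). Lower were YLR046C (-7.97 ± 0.50), RTA1 (-6.42 ± 0.26), ARG3 (-6.17 ± 0.31), YPL088W (-5.10 ± 0.29) and Scer_14.442 (-4.65 ± 0.23). Without parental RPF replicate 1 and without replicate 2 STE3 had 6.99 and 9.07, and YLR046C -9.28 and -6.66. Ribosome biogenesis genes were lower for 83 of 100 (89 adjusted over the list alone), with an adjusted p = 3.2e-14 and adjusted p = 0.67 with an estimated correlation. Respiratory genes were lower for 22 of 26 (24 adjusted over the list alone), with an adjusted p = 5.8e-08 and adjusted p = 0.27 with an estimated correlation. PHO84 rose to 4.01 ± 0.17 (16.2-fold) among 9 higher phosphate genes of 13 (10 adjusted over the list alone), with an adjusted p = 9.6e-05 and adjusted p = 0.23 with an estimated correlation. Of 26 cell wall genes 13 were higher and 4 lower (13 and 5 adjusted over the list alone), among them the chitinase gene CTS1 (4.61 ± 0.13) and TIP1 (3.20 ± 0.20), with an adjusted p = 0.025 and adjusted p = 0.85 with an estimated correlation. Nitrogen catabolite genes went both ways, with 10 of 18 higher and PUT4 lower (-3.77 ± 0.32), and 10 and 1 adjusted over the list alone. DUR1,2 was among the higher ones (3.60 ± 0.28), and the list had an adjusted p = 0.018 and adjusted p = 0.55 with an estimated correlation.

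The limma fit called 2043 genes in parental RPF, 889 higher and 1154 lower in S. cerevisiae, and 1633 with setting weights (708 and 925). With median-of-ratios scaling 1028 were higher and 1006 lower, so the excess of lower genes depended on the scaling. With 1 factor per mixed library for both species instead of the authors' factors, 84 were higher and 83 lower. Against a 1.5-fold difference 561 passed. Genes called in both parental mRNA and parental RPF numbered 1221, and 1203 of these had the same direction, with 572 higher in both against 175.9 for independent lists and 631 lower in both against 216.6. With setting weights 1316 were called in both and 1285 had the same direction.

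In translational efficiency Scer_2.323 (4.77 ± 0.74) and the agglutinin genes SAG1 (4.30 ± 0.35, 19.8-fold) and AGA1 (3.60 ± 0.59, 12.1-fold) were higher in the S. cerevisiae parent. GCV2, for a subunit of glycine decarboxylase, was 4.68-fold higher (2.23 ± 0.25) and PHO84 3.89-fold (1.96 ± 0.24). Lower in S. cerevisiae were YLR046C (-3.95 ± 0.71), BRE4 (-3.36 ± 0.50), Scer_5.203 (-2.38 ± 0.25), the cyclin gene PCL5 (-2.16 ± 0.47) and VHR1 (-2.01 ± 0.30). Of 26 cell wall genes 3 were higher, namely EXG1 (1.41 ± 0.15), YNL066W (1.60 ± 0.24) and CTS1 (1.03 ± 0.18), and 5 were higher and 2 lower adjusted over the list alone. The list had an adjusted p = 0.00036, and adjusted p = 0.67 with an estimated correlation. Among 67 mitochondrial ribosomal protein genes 4 were lower (5 adjusted over the list alone), led by MRPL9 (-0.93 ± 0.20). Camera gave this list an adjusted p = 0.04, adjusted p = 0.68 with an estimated correlation and adjusted p = 0.052 with setting weights.

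For parental TE limma called 201 genes, 81 higher and 120 lower in S. cerevisiae, and 288 with setting weights (111 and 177). With median-of-ratios scaling, which moved the median of all genes by 0.13, 133 were higher and 75 lower, so the balance of directions depended on the scaling. Without parental mRNA replicate 1 the count was 41 and without replicate 2 it was 28. Against a 1.5-fold difference 20 passed, and YLR046C (adjusted p = 0.054), VHR1 (0.053) and PCL5 (0.23) did not. Without replicate 1 and without replicate 2 the calls were lost for YLR046C (-3.79 and -4.10), AGA1 (3.40 and 3.80) and PCL5 (-2.38 and -1.94), without replicate 2 alone for Scer_2.323 (4.67) and VHR1 (-1.56), and without replicate 1 alone for BRE4 (-3.22). That of PCL5 was also lost without parental RPF replicate 2 (-1.21, and -3.12 without replicate 1), and YLR046C had -5.26 without parental RPF replicate 1 and -2.64 without replicate 2.

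The trans part is the parental minus the hybrid difference, so its test is the test of whether the species difference changed between parents and hybrid. Of genes above 106 ppm, the largest values in mRNA were those of the mating genes MF(ALPHA)2 (9.53 ± 0.71), STE3 (8.48 ± 0.68), YLR040C (6.43 ± 0.46) and SAG1 (4.75 ± 0.35). No folds are given for the first pair, whose hybrid values lay near 0. CHA1 followed with 4.56 ± 0.19 (23.5-fold). Negative values belonged to Scer_14.442 (-4.90 ± 0.32), ZRT1 (-3.64 ± 0.61), Scer_15.622 (-3.00 ± 0.16) and the arginine synthesis genes ARG3 (-2.92 ± 0.43) and ARG1 (-2.84 ± 0.20). Below that coverage, the mating gene STE4 had a value of 5.58 ± 1.01 and IME4, a regulator of meiosis, -6.15 ± 0.43. In RPF the values were 10.20 ± 0.68 for STE3, 9.43 ± 0.71 for MF(ALPHA)2, 7.26 ± 0.46 for YLR040C, 6.80 ± 0.35 for SAG1 and 5.53 ± 0.59 for AGA1. On the other side were ZRT1 (-6.12 ± 0.61), Scer_14.442 (-5.36 ± 0.32), ARG3 (-3.88 ± 0.43), Scer_15.622 (-3.36 ± 0.16) and SCM4 (-3.25 ± 0.29), and IME4 had -6.18 ± 0.43. Leaving out hybrid RPF replicate 1 or replicate 2 gave -7.45 or -4.79 for ZRT1 and 4.41 or 6.64 for AGA1, and leaving out parental RPF replicate 1 or replicate 2 gave 9.16 or 11.24 for STE3.

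Ribosome biogenesis genes were lower in trans mRNA for 49 of 100 (76 adjusted over the list alone), with a list median of -0.75, NSR1 at -2.31 ± 0.17 and DBP7 at -1.53 ± 0.22. Camera gave an adjusted p = 4.2e-25, and adjusted p = 0.55 with an estimated correlation. Respiratory genes were lower for 13 of 26 (17 adjusted over the list alone), with a list median of -0.91 and CYC1 at -2.63 ± 0.21, an adjusted p = 2.3e-10 and adjusted p = 0.23 with an estimated correlation. Ergosterol genes were lower for 12 of 20 (15 adjusted over the list alone), with ERG28 at -1.61 ± 0.19, an adjusted p = 2.8e-08 and adjusted p = 0.41 with an estimated correlation. Of 22 genes of general stress and reserve carbohydrate 9 were higher (14 higher and 2 lower adjusted over the list alone), among them TPS1 for trehalose synthesis (1.75 ± 0.18) and TRX1 (1.34 ± 0.19), with an adjusted p = 9.6e-05 and adjusted p = 0.53 with an estimated correlation. Phosphate genes were higher for 8 of 13 (10 adjusted over the list alone), with VTC4 at 2.23 ± 0.17, an adjusted p = 1.5e-05 and adjusted p = 0.23 with an estimated correlation.

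The trans mRNA test called 552 genes in limma, 283 higher and 269 lower, and 1637 with setting weights (874 and 763). With median-of-ratios scaling 220 were higher and 341 lower. Without hybrid mRNA replicate 1 the count was 180, without replicate 2 158, without parental mRNA replicate 1 302 and without replicate 2 179. For trans RPF 1019 genes were called, 434 higher and 585 lower, and 497 with setting weights (211 and 286). Median-of-ratios scaling gave 516 higher and 503 lower there, so that in both tests the balance depended on the scaling. With 1 factor per mixed parental RPF library 28 were higher and 11 lower in trans RPF, and SCM4 (-3.33, adjusted p = 0.11) was not called. Against a 1.5-fold difference 131 and 232 genes passed in trans mRNA and trans RPF. Genes called in both trans mRNA and trans RPF, which share no library, numbered 388, and 387 had the same direction, with 184 higher in both against 27 for independent lists and 203 lower in both against 34.6. With setting weights 410 were called in both, 408 of them in the same direction. For mRNA trans the authors' deposited table called 2879 genes, of which 536 were among the 552 and 1585 among those of the weighted fit.

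For trans TE 2 genes were called, GCV2 (2.57 ± 0.35, 5.95-fold, adjusted p = 0.046) and Scer_3.153 (-1.75 ± 0.25, 3.36-fold, adjusted p = 0.046). With setting weights there were 10 (4 and 6), and with median-of-ratios scaling, which moved the median of all genes by 0.14, GCV2 was the only call. Neither passed against a 1.5-fold difference (adjusted p = 0.17 and 0.35), where limma called 0 genes (90 at an unadjusted p under 0.05). At an unadjusted p under 0.05 limma had 400 genes. In limma 0 were called without hybrid mRNA replicate 1 (253 at an unadjusted p under 0.05), hybrid mRNA replicate 2 (171), parental mRNA replicate 1 (268), parental mRNA replicate 2 (209) or parental RPF replicate 2 (570). The count was 250 without hybrid RPF replicate 1, 5 without replicate 2 and 4 without parental RPF replicate 1. GCV2 was not among the calls without parental RPF replicate 1 (2.58), nor Scer_3.153 without hybrid RPF replicate 2 (-1.73). For translation trans the authors' deposited table called 1287 genes, of which 1 was also called here and 1058 had the same sign.

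Across genes, RPF allele ratios in the hybrid followed mRNA ratios with a slope of 0.84 (95% bootstrap interval 0.78 to 0.90), and in the parents with a slope of 0.96 (0.92 to 0.99). Over the 3584 genes with a mean coverage of at least 50 ppm the slopes were 0.94 (0.87 to 1.01) and 1.00 (0.96 to 1.05), so that neither interval then excluded 1. The mRNA ratio of one replicate and the TE ratio of the other correlated with r = -0.12 in the hybrid and -0.05 in the parents. Of 9 genes called for both cis mRNA and cis TE 7 had opposite directions, and with setting weights 19 of 37. Of 112 genes called for both parental mRNA and parental TE 71 were opposite, and with setting weights 136 of 214. These pairs of tests share their mRNA libraries, and part of any excess of opposite directions comes from that. The slope of the parental on the cis ratio was 0.82 (0.73 to 0.90) in mRNA and 0.87 (0.77 to 0.97) in RPF, below 1 where cis and trans differences oppose each other. Genes are not independent replicates, and these intervals treat them as such.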

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

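The tests of explanation in this part were chosen after the results had been seen, except that of the ATP synthase subunits. Each item given here is a species difference that changed between parents and hybrid, by the interaction test itself in limma or in camera.

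The number of genes whose difference changed was 552 in mRNA, 1019 in RPF and 2 in translational efficiency, and with setting weights 1637, 497 and 10. In simulated data with 200 genes changed 2-fold, the shared spread gave 22.6% false calls for trans RPF. That share depends on how many genes were changed and is not the false share of the 1019 calls. No 2-fold change was recovered for trans TE in the simulation. Among genes with a mean coverage above 106 ppm, the largest positive changes in mRNA were those of MF(ALPHA)2 (9.53), STE3 (8.48), YLR040C (6.43), SAG1 (4.75) and CHA1 (4.56), and the largest negative ones those of Scer_14.442 (-4.90), ZRT1 (-3.64), Scer_15.622 (-3.00), ARG3 (-2.92) and ARG1 (-2.84). In RPF they were those of STE3 (10.20), MF(ALPHA)2 (9.43), YLR040C (7.26), SAG1 (6.80) and AGA1 (5.53), and of ZRT1 (-6.12), Scer_14.442 (-5.36), ARG3 (-3.88), Scer_15.622 (-3.36) and SCM4 (-3.25). In translational efficiency only GCV2 (2.57) and Scer_3.153 (-1.75) were called, and values that did not pass are not ranked. Values of MF(ALPHA)2 and STE3, and that of SAG1 in RPF, rest on hybrid coverage near 0. Weaker genes with larger values, such as IME4 (-6.15 in mRNA and -6.18 in RPF), were not ranked here.

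Gene lists past the test in trans mRNA had list medians of 2.99 for haploid and mating, 0.86 for phosphate, 0.72 for general stress and reserve carbohydrate, 0.70 for purine and pyrimidine synthesis, 0.47 for methionine and sulfur and 0.40 for glycolysis and fermentation. Negative medians there were -0.91 for the respiratory chain and ATP synthase, -0.75 for ribosome biogenesis, -0.73 for ergosterol, -0.39 for branched-chain amino acids, -0.33 for genes with known upstream ORFs, -0.19 for translation factors, -0.15 for mitochondrial ribosomal proteins and -0.13 for the cell cycle. In trans RPF the list medians were 5.27 for haploid and mating, 1.25 for phosphate, 0.91 for histones and silencing, 0.78 for general stress, 0.27 for methionine and sulfur, -1.23 for the respiratory chain, -0.65 for ribosome biogenesis, -0.63 for ergosterol and -0.57 for mitochondrial ribosomal proteins. In trans TE they were 0.20 for cytosolic ribosomal proteins, 0.16 for the cell wall, 0.16 for haploid and mating and -0.33 for mitochondrial ribosomal proteins. None of these list calls held with an estimated correlation, where the adjusted p ran from 0.16 to 0.8. With median-of-ratios scaling each of these medians kept its sign.

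The first pattern is the high level of haploid and mating genes in the S. cerevisiae parent. A loss of S. paradoxus reads in these genes would show in the hybrid too, but the median allele difference there was -0.21 over the 18 called members. Several of them, such as MF(ALPHA)2 and FUS3, had hybrid mRNA coverage near 0 and could not show such a loss. The argument therefore rests on the better covered members, which were not tested apart. The choice between scaling to totals and median-of-ratios scaling moved genes by a median of only -0.05 in parental mRNA. The list median there was 2.83 with the latter, so that choice does not account for the pattern. Neither scaling can show a difference in total output between the species. Ploidy and cell type of the strains may account for the pattern, because the S. paradoxus parent differed from the S. paradoxus allele of the hybrid by a median of 0.15, while the S. cerevisiae parent lay 4.53 above its allele. As 1 strain per species was grown, a species difference in the mating programme itself was not tested.

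The second pattern is the lower level of respiratory and ergosterol genes in S. cerevisiae in trans. Lost S. cerevisiae reads were argued against by a median allele difference of -0.06 for the respiratory list. Median-of-ratios scaling moved genes by a median of only -0.07 in trans mRNA, and the list median was -0.97 with it. The choice between the scalings therefore does not account for the pattern, and a difference in total output was not tested. The genes of the TCA cycle gave no sign of a lower activity of the Hap2/3/4/5 complex. Their list median was 0.35, against a central 95% of -0.33 to 0.33 in matched random lists. HAP4 itself was lower in trans mRNA (-1.56) and trans RPF (-2.03), while HAP2, HAP3 and HAP5 were not called in either. The list follows a pathway, not targets of the complex, so this explanation stays open. Lower activity of the regulator Hap1 may account for the respiratory part, since the ATP synthase subunits, not known as its targets, had a median of -0.38. That lay inside the central 95% of matched random lists (-0.44 to 0.32), but at percentile 4.91 this is weak evidence. HAP1 was not analysed here, the ergosterol part was not covered by that test, and ploidy and growth differences between the parents stay open.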

How the results depend on the processing

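Setting weights, each assay alone, and the removal of ploidy and mating-type genes were alternatives chosen after the data had been seen, and the replicate block in the parents and the common factor for parental RPF were run after the other results. Filters, pseudocounts and the unmasked-length offset moved no count by over 1.5 times, and of the 87 values named for the largest changes 85 kept their call with the offset and 87 with setting weights.

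With setting weights the counts were 1727 for cis mRNA, 552 for cis RPF, 64 for cis TE, 2663 for parental mRNA, 1637 for trans mRNA, 497 for trans RPF and 10 for trans TE. With each assay alone they were 1671 for cis mRNA, 673 for cis RPF, 2767 for parental mRNA, 1647 for trans mRNA and 544 for trans RPF. Against a 1.5-fold difference limma gave 59, 193 and 3 in cis, 410, 561 and 20 in parents and 131, 232 and 0 (90 at an unadjusted p under 0.05) in trans, each for mRNA, RPF and TE. Without the library block there were 56 for cis TE and 9 for trans TE, with the hybrid alone 12 for cis TE, and with median-of-ratios scaling 1 for trans TE. By construction these alternatives change the spread or the hypothesis, and for the scaling the cause was not tested.

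Leaving out 1 replicate, which in parental mRNA may be a pair of libraries, leaves a setting with 1 ratio. That ratio is assumed to vary like the others, and the spread of its setting is dropped from the shared one. Counts then ranged from 44 to 75 for cis mRNA, 707 to 1451 for cis RPF, 0 to 634 for cis TE, 663 to 824 for parental mRNA, 1452 to 1583 for parental RPF, 28 to 190 for parental TE, 158 to 302 for trans mRNA, 781 to 1455 for trans RPF and 0 to 250 for trans TE. Where limma called 0, the genes at an unadjusted p under 0.05 numbered 463 and 284 for cis TE and 253 and 171 for trans TE without a hybrid mRNA library, and 268, 209 and 570 for trans TE without parental mRNA replicate 1, replicate 2 and parental RPF replicate 2. Without either parental mRNA replicate, which enters through the shared spread alone, fewer genes were called for cis TE.

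Same-numbered mRNA and RPF replicates did not deviate together in the hybrid (correlation across genes of 0.02, and 0.18 in the parents), so the numbers were not taken to pair libraries. With a replicate block in the hybrid cis mRNA had 577, cis RPF 1196, cis TE 26, trans mRNA 524, trans RPF 1023 and trans TE 0 (408 at an unadjusted p under 0.05). BUD3 and IDP1 (adjusted p = 0.052 each) and LYS4 (0.053) were then not called for cis TE, nor GCV2 and Scer_3.153 (0.062 each) for trans TE. With a block in the parents, whose mRNA numbers stand in no label, parental TE had 259. With blocks in hybrid and parents cis TE had 78, trans mRNA 670, trans RPF 1135 and trans TE 10, the last with GCV2 and Scer_3.153 among them.

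Over genes with a mean coverage of at least 50 ppm the RPF slope on mRNA was 0.94 in the hybrid, still below 1 but with an interval that included it, and 1.00 in the parents. The cause was not tested there. With 1 factor per parental RPF library for both species, parental RPF had 167 (84 higher) and trans RPF 39 (28 higher). By construction this adds the authors' factors of 2.13 and 0.417 to the spread. It was not run for parental mRNA, whose mixed library is not identified. Also not run were a count-based test, since the values are coverage, and the lanes of parental RPF replicate 2 one by one, which have no columns of their own.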

Other observations

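The tests in this part, and the genes named in it, were chosen after the results had been seen, except that the slope with replicates split, and its alternative over genes of at least 50 ppm, were planned as values. Their use as tests of explanations was chosen afterwards. Genes with a TATA box in their promoter, as marked in the deposited table, had larger mRNA differences than genes without one. The spread of ratios shared by both replicates was 0.64 over 496 TATA genes and 0.37 over 2971 others in cis mRNA, 1.05 and 0.62 in parental mRNA, and 0.91 and 0.51 in trans mRNA. Each had an adjusted p = 3e-05 in a two-sided permutation test of ranks within classes of coverage, where 1e-05 is the smallest p that 100000 permutations can give. For cis TE the spread was 0.33 and 0.34 (adjusted p = 0.93). Of 9 relations tested, promoter divergence and coding divergence went with larger cis mRNA differences, with Spearman's rho of 0.07 (adjusted p = 0.0022) and 0.08 (adjusted p = 0.0079). Divergence of the 5′ UTR had a rho of 0.01 with cis TE (adjusted p = 0.89). Genes are not independent replicates, so these p-values describe this set of genes.

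GCN4, the activator of amino acid synthesis genes whose mRNA carries upstream reading frames, had a parental mRNA difference of -0.14 ± 0.13 (SE) and a parental RPF difference of -1.89 ± 0.13. Its parental TE difference was -1.76 ± 0.18 (adjusted p = 0.00085 in limma), and its trans TE difference of -1.55 ± 0.25 did not pass (adjusted p = 0.063). IME4, a regulator of meiosis, stood at 0.519 and 0.595 ppm in S. cerevisiae parental mRNA, at 91.6 and 98 in the S. paradoxus parent and at 78.3 and 80.5 for the S. cerevisiae allele of the hybrid. AMN1, which acts in daughter cell separation and is a member of the haploid and mating list, was higher in the S. cerevisiae parent by 2.20 ± 0.18. Its cis mRNA value was -0.13 ± 0.18. For IME4 and AMN1 the ploidy of the parents was not tested apart from species.

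The slope of RPF on mRNA allele ratios in the hybrid lay below 1. Shared error between the ratios as its whole cause was argued against by a slope of 0.84 with replicates split, whose interval of 0.78 to 0.90 excluded 1. Weakly covered genes may account for it, since over genes with a mean coverage of at least 50 ppm the slope was 0.94 and its interval of 0.87 to 1.01 included 1. Against this, the rank correlation of mRNA and TE ratios with replicates split was -0.11 over all genes and -0.12 over those at 50 ppm or more. A real opposition of mRNA and translation differences therefore stays open.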
